A study of Homo sapiens with 4 samples.

How the data were processed

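Poly(A) RNA of 4 libraries was sequenced after extraction with a column kit and stranded library preparation, per the labels' protocols: KMS21 and KMS34 myeloma cells, untreated or with ambroxol (given in the labels as 200 mM, a unit open to doubt, for 24 h). The submitters' processing notes list Trimmomatic, STAR 2.7.9a and the hg38 build. The quantification tool and annotation release were not given in the sources used here.

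The authors deposited 1 table of 57955 Ensembl genes with symbols and hg38 coordinates, which holds 2 values per gene and library. The first is log2 TPM (corrected for gene length), which the authors listed as 0 wherever TPM was 1 or less, per the workbook's explanation sheet. The second is a deposited estimated count of reads per gene, not normalised. Of the estimated counts above 0, 83.4 to 84.5% were not whole numbers, so reads that fit several genes appear to have been divided between them, and values of near-identical or overlapping genes are uncertain. Of the gene IDs, 99.0% (57351) were in GENCODE release 29, 96.3% of these with identical coordinates. The table holds nuclear chromosomes, and mitochondrial transcripts were not analysed here.

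The tests had been planned for TPM values with limma. Because counts were found, the estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3), and the planned limma 3.58.1 fit on log2(TPM + 1) became an alternative. Genes with TPM above 1 in at least 2 of the 4 libraries were kept (15703). Counts were scaled by TMM (factors 0.894, 0.887, 1.12 and 1.13 in the order KMS21 untreated, KMS21 ambroxol, KMS34 untreated, KMS34 ambroxol), and per-library values are CPM, with log2 CPM at a prior count of 2. The quasi-likelihood test, two-sided with Benjamini-Hochberg adjustment, had terms for line and treatment and 1 residual degree of freedom per gene, moderated over genes. The lines pair the libraries: the 2 libraries of a line come from the same cell line and correlated at 0.963 and 0.988, against at most 0.725 between lines. Within a line there is 1 library per arm and no test, so values and counts of genes at least 2-fold apart are given. The difference between the lines' responses was not tested gene by gene.

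The 38 gene lists were fixed before the data were examined, and 961 of their genes were matched by ID or symbol. The 33 lists with at least 5 genes past the filter were tested across both lines with camera (limma) at a preset correlation of 0.01, two-sided with Benjamini-Hochberg adjustment over the lists. Of these, 15 rose and 8 fell. With an estimated correlation 0 lists held, and the smallest adjusted p was 0.599. That setting rests on 1 residual degree of freedom, so it had little power to call any list and cannot tell moved from unmoved lists. The estimated correlations rest on the same 1 degree of freedom. They were 1 for DNA replication and mitosis, 0.86 for lysosomal genes and 0.02 for ATF4 targets, against the preset 0.01. Where genes of a list move together more than the preset allows, the preset p-values are too small. Fry, which tests whether a list's genes move on balance one way, passed 1 list, the immediate early genes (adjusted p = 0.0094). Per line, each list's median was set against 10000 random lists of the same size matched on mean expression, as a description of those libraries. In 12 lists a member had 0 counts in a library, and setting such members to the bound of a 3-count floor moved a list's median by at most 0.017.

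Named genes were chosen by a rule fixed before the data were examined: the 12 higher and 12 lower genes with mean TPM of at least 5 and the greatest smaller-of-both-lines difference, up to 4 members per list with the greatest mean difference, the 5 genes per direction whose differences differ most between the lines, the 5 per direction with the greatest line difference, and SQSTM1, MAP1LC3B, LAMP1, LAMP2, TFEB, MYC, IRF4, XBP1, DDIT3, BCL2 and MCL1, with some further items that are not reported here. Immunoglobulin and T cell receptor segments, clone-named genes, pseudogenes and small RNAs were left out of the rules by size. Not all named genes are printed. UAP1L1, FAM178B and FOXJ1, which had few counts in a line, are among those left out.

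The depth of 36535658 to 52326580 counts per library puts a floor of 3 counts at 0.061 to 0.092 CPM. Intervals and floors cover counting error only. The 10 most abundant genes took 11.0, 9.90, 5.84 and 5.83% of the counts, and immunoglobulin genes 4.25, 4.39, 2.59 and 2.51%, in the order above.

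The scripts were tested on simulated data before use. Counts for 15703 genes were drawn from the libraries' means and sizes with the estimated spread, and 50 genes each were changed by a known log2 fold. For the comparison across both lines, 8 of 50 genes were recovered at log2 1, 46 at 2, 49 at 3 and 50 at 4, and 6 of 15503 unchanged genes were called. The simulated effects were the same in both lines and the spread followed expression level alone, so recovery in the real data may be lower. For the list test, a list of 30 genes shifted by 0.5 gave a camera p of 1.0e-10, and 0 of 40 unchanged lists had a p under 0.05. The simulated genes were drawn independently of each other, so this check cannot show how the preset correlation performs where genes of a list move together.

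The alternatives were limma on log2(TPM + 0.1) and log2(TPM + 5), no filter on low values, a mean TPM of at least 5, median-ratio scaling, removal of immunoglobulin genes with scaling by totals, protein-coding genes only, no replicate block, no variance trend, each line left out in turn, an estimated correlation and fry. Limma on log2(TPM + 1), first planned as the main test, is also given as an alternative, and DESeq2 1.42.0 was added after the data were seen.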

Results

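RNA was sequenced from KMS21 and KMS34, established human multiple myeloma cell lines grown from malignant plasma cells, each untreated and after 24 h with ambroxol, a mucolytic drug that accumulates in acidic compartments such as lysosomes. The labels give the dose as 200 mM, and its unit was not checked against another source and is open to doubt. The series asked how ambroxol inhibits autophagy in myeloma cells. Each of the 4 groups had 1 library, so differences within a line have no replicate check and the 2 lines are the only replication of the treatment. The libraries held 36535658 (KMS21 untreated), 52326580 (KMS21 ambroxol), 44224199 (KMS34 untreated) and 37363234 (KMS34 ambroxol) counts, and 15703 genes passed the filter on low values. Values below are normalised read counts in CPM, scaled to library size, and log2 differences, ambroxol minus untreated. No label says whether the cultures of the lines were grown apart in time, so p-values measure only the spread between these libraries. For the treatment, that spread is how unlike the 2 lines responded, moderated over genes. It cannot be told apart from variation between cultures, and a gene that moved in both lines by unequal amounts can fail to pass.

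The first comparison asked which genes differed after ambroxol in the same way in both lines. CCL3, which encodes a chemokine, was higher from 8.09 to 214 CPM in KMS21 and from 21.5 to 417 CPM in KMS34, a log2 difference of 4.50 ± 0.28 (SE) across both lines. CCL3 lies at 36088256 to 36090169 on chromosome 17 (hg38). DDIT3, which encodes the stress-induced transcription factor CHOP, was higher from 15.1 to 65.8 CPM in KMS21 and from 22.8 to 119 CPM in KMS34. TRIB3, a pseudokinase gene induced by ATF4 and CHOP, was higher by log2 1.74 in KMS21 and 1.71 in KMS34. ADCY1 (2.69 and 1.88), which encodes an adenylyl cyclase, FBXO32 (4.15 and 1.74), which encodes a ubiquitin ligase subunit, DPYSL2 (2.54 and 1.72), LURAP1L (3.84 and 1.91) and TMEM255A (4.60 and 1.76) were also higher in both lines. CCL3L3, a near-identical copy of CCL3, went from 42 to 2326 counts in KMS21 and from 0 to 22 counts in KMS34, and reads may have been divided between the copies. Among genes lower in both lines were the cyclin E genes CCNE1 (-2.33 in KMS21, -1.01 in KMS34) and CCNE2 (-4.59 and -1.12), MIR17HG, the host transcript of a microRNA cluster (-3.71 and -1.63), and CXCR3, a chemokine receptor gene (-2.76 and -1.37). The mitochondrial tRNA methyltransferase subunit gene TRMT10C (-1.49 and -1.11) and the carbonic anhydrase gene CA2 (-3.51 and -1.07) were also lower, as were the small nucleolar RNA host transcripts SNHG4 (-1.80 and -1.44) and SNHG3 (-1.495 and -1.01), which overlap other genes on the same strand. The size of some KMS21 differences rests on few reads. There MIR17HG went from 74 to 6 counts, CA2 from 176 to 20, CXCR3 from 123 to 24, CCNE2 from 461 to 25 and TMEM255A from 14 to 532.

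No gene passed an adjusted p of 0.05 across both lines with edgeR's quasi-likelihood test, line as block and Benjamini-Hochberg adjustment. The smallest adjusted p was 0.0847, for CCL3. At an unadjusted p under 0.05 there were 1643 genes, 985 higher and 658 lower, where 785 would be met by chance. Limma on log2(TPM + 1) also called 0 genes, with 1645 at an unadjusted p under 0.05. DESeq2, added after the data were seen, called 150 genes, 127 higher and 23 lower, and had 1470 at an unadjusted p under 0.05. With no filter on low values edgeR called 88 genes, 83 higher and 5 lower. DESeq2's calls included CCL3, DDIT3 (adjusted p = 1.1e-12), TRIB3 (1.0e-12), SQSTM1 (5.2e-06), BCL2 (3.9e-07) and ERN1 (9.8e-10). With edgeR the adjusted p was 0.38 for DDIT3 and 0.47 for TRIB3, SQSTM1, BCL2 and ERN1. Both tests used the same 4 libraries with 1 residual degree of freedom, so DESeq2's small p-values add no replication.

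**Figure D1:**
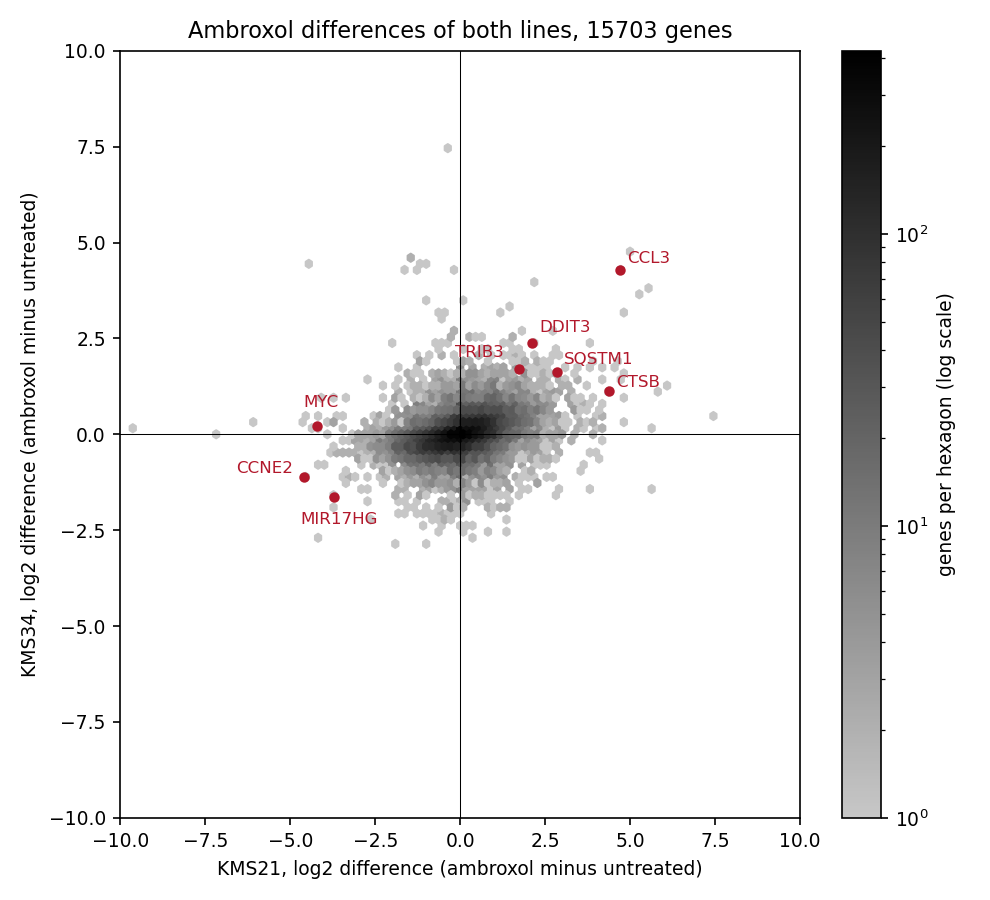
Log2 difference, ambroxol minus untreated, in KMS21 (horizontal axis) against KMS34 (vertical axis) for 15703 genes, with hexagons shaded by the number of genes on a log scale and 8 genes marked in red. The cloud is wider along the KMS21 axis, where the SD of the differences was 0.913, than along the KMS34 axis, where it was 0.511, and CCL3 stands at 4.72 and 4.28.

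Genes of autophagy and the lysosome were examined as lists fixed before the data were examined. The adjusted p with an estimated correlation, given beside each call, rests on 1 residual degree of freedom. At its smallest over the tested lists it was 0.599, so it cannot tell lists apart. The preset p-values are too small where genes of a list move together more than the preset correlation of 0.01 allows. The lysosomal hydrolases and membrane proteins rose as a list, with a median log2 difference of 0.93 in KMS21 and 0.35 in KMS34, and 45 of 56 measured members were higher in both lines while 0 were lower in both (camera with preset correlation, adjusted p = 5.1e-16, and adjusted p = 0.599 with an estimated correlation). CTSB, which encodes the protease cathepsin B, was higher from 260 to 5447 CPM in KMS21 and from 244 to 531 CPM in KMS34. CTSS, another cathepsin gene (1.72 and 0.81), SLC17A5, the lysosomal sialic acid exporter gene (1.82 and 0.77), LAMP2 (1.43 and 0.45) and LAMP1 (0.67 and 0.25) were higher in both. The autophagy receptors rose (median 0.56 in KMS21 and 0.39 in KMS34, 13 of 18 higher in both, adjusted p = 4.9e-06, and adjusted p = 0.599 with an estimated correlation), and 5 members passed when adjusted over the list alone, all higher. They included SQSTM1, which encodes the cargo receptor p62, from 559 to 4055 CPM in KMS21 and from 84.9 to 264 CPM in KMS34, together with OPTN (2.66 and 1.15), CALCOCO1 (1.83 and 0.76) and CCPG1 (2.61 and 1.40), a receptor gene of ER-phagy. CCPG1 overlaps another gene on the same strand. The core autophagy machinery rose (median 0.39 and 0.22, 23 of 36 higher in both, adjusted p = 0.00059, and adjusted p = 0.599 with an estimated correlation), with WIPI1 at 1.30 and 1.32 the member that passed when adjusted over the list alone (adjusted p = 0.047). MAP1LC3B, which encodes the autophagosome marker LC3B, was at 2.35 and 0.71, and ULK1, the initiating kinase gene, at 1.11 and 0.52.

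The autophagosome-lysosome fusion list rose (median 0.52 and 0.26, 18 of 20 higher in both, adjusted p = 9.8e-05, and adjusted p = 0.599 with an estimated correlation), with EPG5, a tethering factor gene, at 2.23 and 0.83 and RUBCN, whose product restrains fusion, at 2.63 and 0.59. The list of TFEB regulators and mTORC1 feedback rose (median 0.40 and 0.18, 16 of 24 higher in both, adjusted p = 0.00030, and adjusted p = 0.599 with an estimated correlation). Its members with the greatest mean difference encode parts of the machinery that senses amino acids at the lysosome: RRAGC (2.22 and 0.91), FNIP2 (2.20 and 0.92), FNIP1 (1.53 and 0.99) and FLCN (1.73 and 0.68). RRAGC, FNIP1 and FLCN overlap other genes on the same strand, so part of their counts is uncertain. TFEB itself, the gene of the factor that drives lysosomal genes, was at -0.20 in KMS21 and 0.48 in KMS34. The V-ATPase subunits, which acidify the lysosome, did not pass (median 0.22 and 0.17, 14 of 19 higher in both, adjusted p = 0.088), but passed with limma on log2(TPM + 1) (adjusted p = 0.033), and the adjusted p ranged from 0.022 to 0.599 over the alternatives, 0.599 being that with an estimated correlation. The subunits lay at percentile 89.8 of matched random lists in KMS21 and 98.7 in KMS34. Counts of the V-ATPase gene ATP6V0C, which shares its strand and position with 3 other annotated genes, cannot be separated from theirs.

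**Figure D2:**
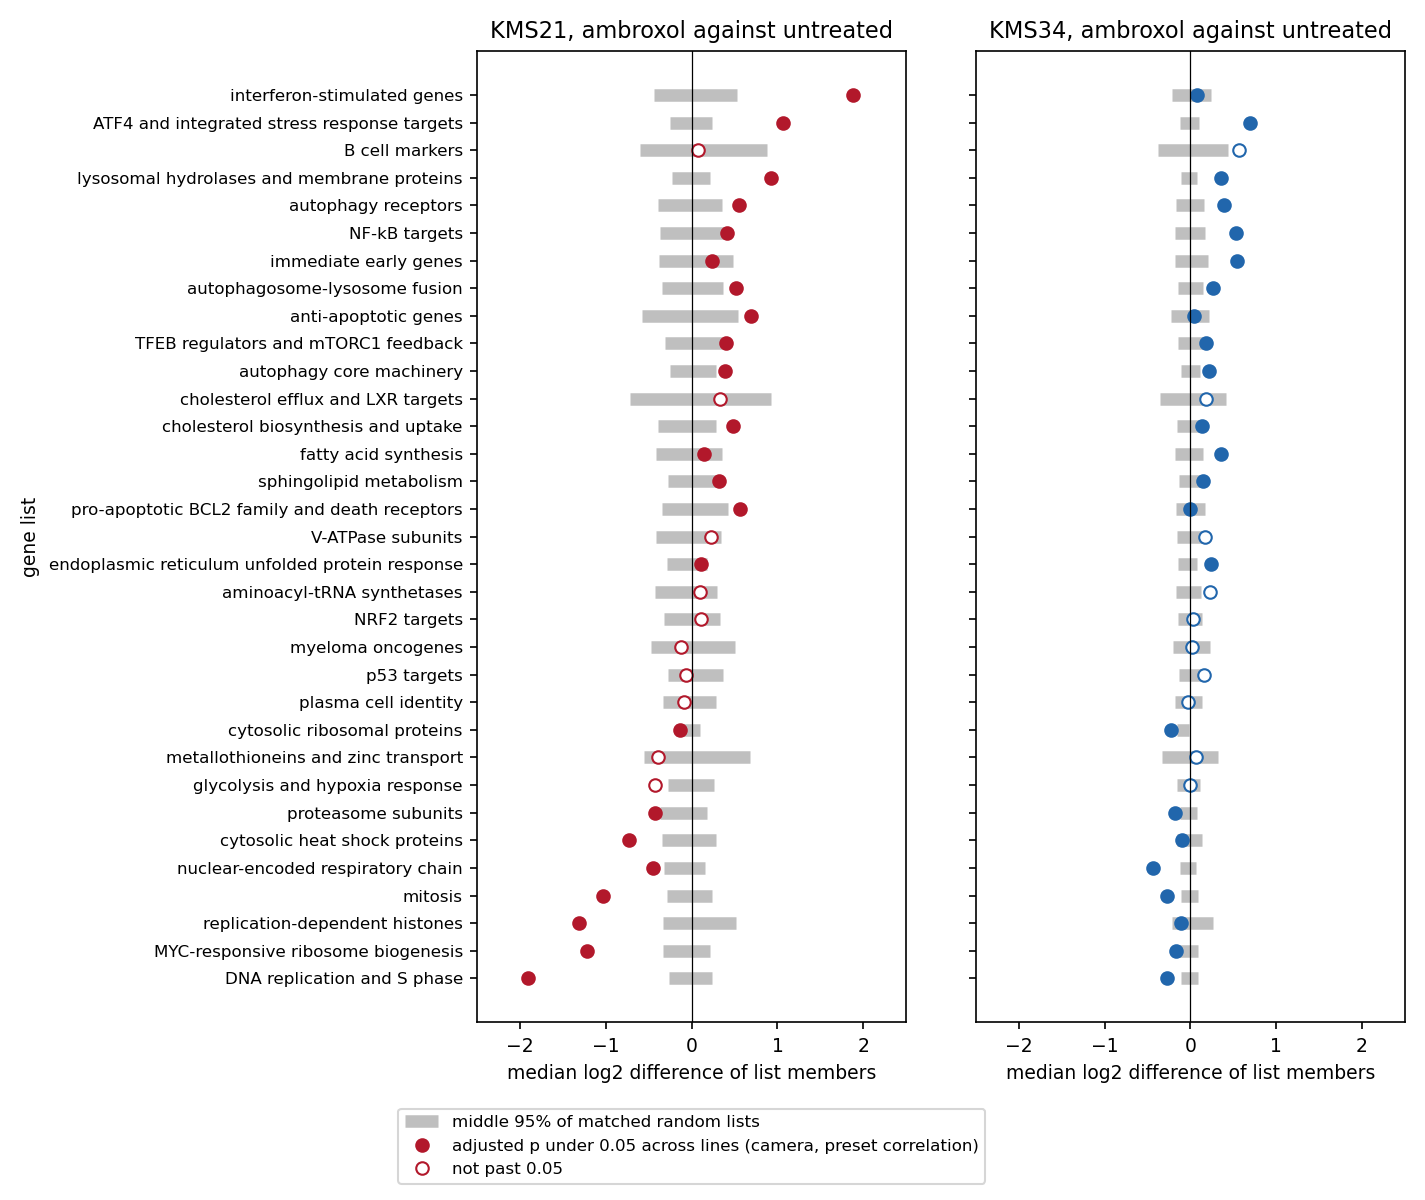
Median log2 difference, ambroxol minus untreated, of the 33 tested gene lists in KMS21 (left) and KMS34 (right), with grey bars for the middle 95% of 10000 random lists of the same size and expression, and filled points for lists with an adjusted p under 0.05 across both lines (camera, preset correlation). The ATF4 list lies at 1.07 and 0.70 and the DNA replication list at -1.91 and -0.27.

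The stress responses were compared in the same way. Targets of ATF4 and the integrated stress response rose, with a median of 1.07 in KMS21 and 0.70 in KMS34, and 33 of 38 measured members were higher in both lines and 0 lower in both (adjusted p = 2.4e-28, and adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone, 23 of these genes passed, all higher. INHBE, a hormone subunit gene, was at 4.17 and 1.53, and CTH, an enzyme gene of cysteine synthesis, at 3.10 and 1.36. GDF15, the gene of a stress-induced secreted factor, went from 2 to 159 counts in KMS21, a ratio of 56.0 (95% counting interval 15.3 to 466), and from 4 to 146 counts in KMS34. The list of the endoplasmic reticulum unfolded protein response rose (median 0.11 and 0.24, 20 of 35 higher in both, adjusted p = 0.0014, and adjusted p = 0.599 with an estimated correlation), and 5 members passed when adjusted over the list alone, among them the sensor genes ERN1 (1.998 and 1.56) and EIF2AK3 (1.55 and 0.88) and the ER-associated degradation genes SEL1L (1.59 and 1.11) and HERPUD1 (0.94 and 1.15). XBP1 was at -0.96 and -0.12. In KMS21 this list lay at percentile 92.3 of matched random lists, within their middle 95%. The aminoacyl-tRNA synthetases did not pass (median 0.10 and 0.23, adjusted p = 0.24), with AARS at 1.13 and 0.75 and FARSB at -1.81 and -0.03. They lay at percentile 83.3 of matched random lists in KMS21 and 99.97 in KMS34.

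Cytosolic heat shock proteins fell as a list (median -0.73 in KMS21 and -0.10 in KMS34, 14 of 22 lower in both, adjusted p = 0.0037, and adjusted p = 0.599 with an estimated correlation). HSPA8, which encodes the chaperone HSC70, went from 3649 to 1054 CPM in KMS21 and from 2334 to 1783 CPM in KMS34. In KMS34 this list lay at percentile 13.5 of matched random lists. The proteasome subunits fell (median -0.43 and -0.18, 33 of 38 lower in both, adjusted p = 8.5e-06, and adjusted p = 0.599 with an estimated correlation), with PSME2, an activator subunit gene, at -1.13 and -0.50 and PSMB3 at -0.78 and -0.61. NRF2 targets did not pass (median 0.10 and 0.03, adjusted p = 0.40), although the ferritin genes FTL (1.49 and 0.65) and FTH1 (1.08 and 0.99) were higher in both lines. Metallothioneins and zinc transport did not pass either (median -0.39 and 0.06, adjusted p = 0.47).

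Lipid genes were examined because ambroxol is a cationic amphiphilic drug. Cholesterol biosynthesis and uptake rose (median 0.48 in KMS21 and 0.14 in KMS34, 15 of 25 higher in both, adjusted p = 0.0026, and adjusted p = 0.599 with an estimated correlation), with the lanosterol synthase gene LSS at 1.21 and 0.62 and INSIG1 at 0.57 and 0.88. Fatty acid synthesis rose (median 0.15 and 0.35, 8 of 17 higher in both, adjusted p = 0.019, and adjusted p = 0.599 with an estimated correlation), with the acetyl-CoA synthetase gene ACSS2 at 1.495 and 0.93. Sphingolipid metabolism rose (median 0.32 and 0.15, 15 of 29 higher in both, adjusted p = 0.014, and adjusted p = 0.599 with an estimated correlation), with the ganglioside synthase gene ST3GAL5 at 2.84 and 1.06 and the ceramide synthase gene CERS4 at 1.93 and 1.13. The 5 measured genes of cholesterol efflux and LXR targets did not pass (median 0.33 and 0.18, adjusted p = 0.97), and across both lines their median (0.26) and mean (-0.02) differed in sign. In KMS21 fatty acid synthesis lay at percentile 82.8 of matched random lists and sphingolipid metabolism at 96.5. The call of sphingolipid metabolism was also lost with limma on log2(TPM + 0.1) (adjusted p = 0.070, from 0.0026 to 0.599 over the alternatives).

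Cell death genes went both ways within their lists. Pro-apoptotic BCL2 family and death receptor genes rose by the preset test (adjusted p = 0.010, and adjusted p = 0.599 with an estimated correlation), with a median of 0.57 in KMS21 and 0 in KMS34 and 7 of 19 higher in both. BBC3, which encodes PUMA, was at 1.62 and 1.32 and HRK at 1.76 and 1.11, and both passed when adjusted over the list alone. BCL2L11, which encodes BIM, was at 2.58 in KMS21 and 0.37 in KMS34, and BMF at 2.92 and -0.09. Anti-apoptotic genes also rose (median 0.69 and 0.04, 3 of 9 higher in both, adjusted p = 0.035, and adjusted p = 0.599 with an estimated correlation), with BCL2 at 1.85 and 1.44 the member that passed when adjusted over the list alone (adjusted p = 0.0057), while MCL1, a survival gene of myeloma cells, was at -0.08 and 0.22. In KMS34 the pro-apoptotic list lay at percentile 48.7 of matched random lists and the anti-apoptotic list at 67.7. The pro-apoptotic call was also lost with limma on log2(TPM + 0.1) (adjusted p = 0.070, from 0.0028 to 0.599 over the alternatives). The anti-apoptotic call was also lost in the 3 limma settings, without the low-value filter and with no variance trend (adjusted p = 0.070 to 0.090, from 0.026 to 0.599 over the alternatives). The p53 targets did not pass (median -0.07 and 0.16, adjusted p = 0.18), and across both lines their median (-0.05) and mean (0.14) differed in sign. They lay at percentile 23.6 of matched random lists in KMS21 and 97.9 in KMS34.

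Plasma cell and myeloma genes did not pass as lists. Plasma cell identity had a median of -0.09 in KMS21 and -0.03 in KMS34 (adjusted p = 0.35), with GPRC5D, a myeloma surface antigen gene, at -1.37 and -0.60 and IRF4, a transcription factor gene on which myeloma cells depend, at -1.12 and 0.14. Myeloma oncogenes had a median of -0.13 and 0.02 (adjusted p = 0.77). MYC, at 127735434 to 127741434 on chromosome 8 (hg38), went from 596 to 32.1 CPM in KMS21 and from 946 to 1104 CPM in KMS34.

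Lists of proliferation genes fell. DNA replication and S phase genes fell with a median of -1.91 in KMS21 and -0.27 in KMS34, 39 of 42 being lower in both (adjusted p = 8.4e-22, and adjusted p = 0.599 with an estimated correlation). All 42 were at least 2-fold lower in KMS21, against 2 in KMS34. RRM2, a ribonucleotide reductase subunit gene, went from 418 to 23.6 CPM in KMS21 and from 252 to 152 CPM in KMS34. Mitosis genes fell (median -1.03 and -0.28, 32 of 37 lower in both, adjusted p = 5.0e-13, and adjusted p = 0.599 with an estimated correlation), with the cyclin genes CCNA2 at -1.85 and -0.38 and CCNB1 at -1.40 and -0.61. Replication-dependent histones fell (median -1.31 and -0.11, 10 of 19 lower in both, adjusted p = 0.00048, and adjusted p = 0.599 with an estimated correlation), and their reads may be shared between near-identical copies. Poly(A) RNA was sequenced, and how fully it holds histone transcripts was not checked, so their values may not follow their total RNA. In KMS34 the histones lay at percentile 10.15 of matched random lists. MYC-responsive ribosome biogenesis genes fell (median -1.22 and -0.17, 28 of 35 lower in both, adjusted p = 2.3e-11, and adjusted p = 0.599 with an estimated correlation), with the nucleolar gene NOP56 at -1.83 and -0.27. The 74 cytosolic ribosomal protein genes fell (median -0.14 and -0.22, 48 lower in both, adjusted p = 0.0044, and adjusted p = 0.666 with an estimated correlation), and in KMS21 lay at percentile 15.4 of matched random lists.

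The nuclear-encoded respiratory chain fell to a like extent in KMS21 (median -0.45) and KMS34 (-0.44), and 46 of 49 members were lower in both (adjusted p = 6.9e-11, and adjusted p = 0.599 with an estimated correlation). NDUFA9, a complex I subunit gene that overlaps other genes on the same strand, was at -0.88 and -0.78. The ATP synthase gene ATP5G3 was at -0.97 and -0.61 and COX7B, of complex IV, at -0.86 and -0.64. Glycolysis and hypoxia response did not pass (median -0.43 and -0.01, adjusted p = 0.31), with PDK1 at -1.96 and -0.30 and BHLHE40 at 3.39 and 1.39. That list lay at percentile 0.23 of matched random lists in KMS21 and 61.4 in KMS34. Targets of NF-kB rose (median 0.41 and 0.54, 13 of 20 higher in both, adjusted p = 3.7e-08, and adjusted p = 0.599 with an estimated correlation), and 3 passed when adjusted over the list alone, namely CCL3, another chemokine gene, CCL4, (5.56 and 3.75, from 4 counts in KMS21 untreated) and ICAM1, an adhesion molecule gene (1.13 and 1.11). Immediate early genes rose (median 0.24 and 0.55, 8 of 16 higher in both, adjusted p = 0.0017, and adjusted p = 0.599 with an estimated correlation). Among them DUSP5, a phosphatase gene, was at 3.33 and 0.74 and KLF2 at -3.31 and -0.19. In KMS21 the NF-kB list lay at percentile 97.15 of matched random lists and the immediate early list at 82.3. Interferon-stimulated genes rose by the preset test (adjusted p = 1.4e-06, and adjusted p = 0.599 with an estimated correlation), with a median of 1.88 in KMS21 and 0.08 in KMS34. In KMS21, 12 of 15 were at least 2-fold higher, such as OAS1 (from 13.9 to 140 CPM), against 2 in KMS34, where OAS1 went from 13.9 to 14.1 CPM and the list lay at percentile 77.2.

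**Figure D3:**
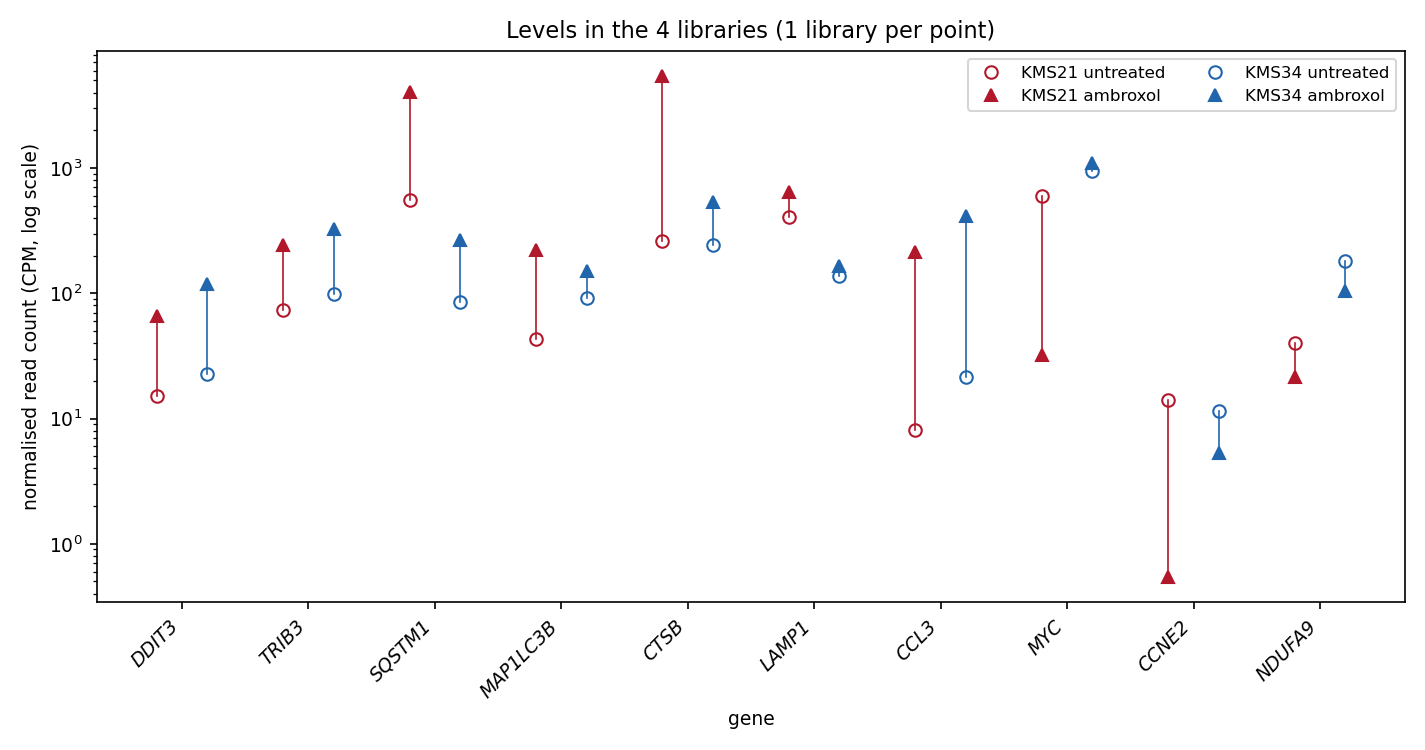
Normalised read count (CPM, log scale) of 10 genes in the 4 libraries, 1 library per point, with open circles for untreated and filled triangles for ambroxol, KMS21 in red and KMS34 in blue, and lines that join the libraries of a line. MYC went from 596 to 32.1 CPM in KMS21 and from 946 to 1104 CPM in KMS34, while CCL3 was higher after ambroxol in both.

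Within each line, the number of genes at least 2-fold apart describes those 2 libraries. In KMS21, 3343 genes (21.3%) were at least 2-fold apart, 1765 higher and 1578 lower after ambroxol. In KMS34 there were 916 (5.83%), 564 higher and 352 lower. Among protein-coding genes there were 2427 in KMS21, where the balance turned to 1198 higher and 1229 lower, and 431 in KMS34, 341 higher and 90 lower. The lines shared 225 genes higher and 79 lower, where independent lists would share 63.4 and 35.4, and 92 genes went opposite ways where 96.2 would. Across genes, which are not independent replicates, the log2 differences of the lines had a Pearson r of 0.330 and a Spearman rho of 0.404. The genes whose differences lay farthest apart between the lines included CDKN1C, a cell cycle inhibitor gene (7.52 in KMS21, 0.52 in KMS34), and RGS1, a regulator of G protein signalling (28.5 to 1890 CPM in KMS21, 4.66 to 10.8 CPM in KMS34). CT45A1, CT45A3, CT45A5, CT45A6 and CT45A7, near-identical cancer-testis genes among which reads cannot be assigned with certainty, were 4.30 to 4.57 higher in KMS34 and lower in KMS21.

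The lines differed from each other far more than treated from untreated cells. Libraries of the same line correlated at 0.963 (KMS21) and 0.988 (KMS34) over log2 CPM, against 0.703 to 0.725 between lines. In the same edgeR fit 6176 genes differed between the lines at an adjusted p under 0.05, 2959 higher in KMS34 and 3217 higher in KMS21. FGFR3, a receptor tyrosine kinase gene activated by translocation in some myelomas, was at 580 CPM in KMS34 untreated and 0.123 CPM in KMS21 untreated (adjusted p = 0.00024). CCND2, a cyclin D gene, was at 257 CPM in KMS34 untreated with 0 counts in both KMS21 libraries. MAGEA4, a cancer-testis antigen gene, was at 1172 CPM in KMS21 untreated with 0 counts in KMS34 untreated, and MAEL was at 524 CPM in KMS21 untreated with 0 counts in both KMS34 libraries. MAF, an oncogene of some myelomas, was at 172 CPM in KMS34 untreated with 0 counts in KMS21 untreated.

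Among markers of other cell types, the highest myeloid marker was CD68 at 5.70 TPM in KMS21 ambroxol, itself a lysosomal membrane protein gene. T and NK cell markers reached 21.7 TPM (CD3E, KMS21), stromal and endothelial markers 13.8 TPM (PECAM1, KMS34) and erythroid markers 18.2 TPM (HBD, KMS34). B cell markers, some of which myeloma lines express, reached 46.6 TPM (CR2, KMS21), and as a list did not pass (median 0.07 in KMS21 and 0.57 in KMS34, adjusted p = 0.095), but passed without the low-value filter (adjusted p = 0.017, from 0.017 to 0.648 over the alternatives). The B cell list lay at percentile 47.2 of matched random lists in KMS21 and 99.35 in KMS34.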

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

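Of the tests reported here, that of a uniformly smaller response was chosen only after the result was seen. Because each group has 1 library, no sample was tested for standing apart from its group, and the differences between the lines given next were not tested.

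Among the named genes, 16 went up after ambroxol in one line and down in the other, beyond counting error in both, and are given as the log2 difference in KMS34 minus that in KMS21. Genes lower in KMS21 and higher in KMS34 were MYC (4.44), PLK2, a kinase gene among the p53 targets (4.34), the chaperone gene HSPA4L (1.83), IRF4 (1.26), TFEB (0.68) and MCL1 (0.30). MYC was at -4.21 in KMS21 and 0.22 in KMS34. The cancer-testis genes CT45A7 (6.02), CT45A5 (5.999), CT45A6 (5.99), CT45A1 (5.66) and CT45A3 (5.62) went the same way, and as near-identical copies they count as 1 observation. Genes higher in KMS21 and lower in KMS34 were CD52, a lymphocyte surface antigen gene (-7.08), the cytokine receptor gene CRLF2 (-5.23), the interferon-stimulated gene MX1 (-4.70), RGS9 (-4.41) and the adhesion gene PECAM1 (-1.39). In KMS34, CD52 went from 16 to 4 counts and CRLF2 from 14 to 3, a ratio of 0.252 (95% counting interval 0.046 to 0.903) for CRLF2, so their direction there rests on few reads. The CT45A genes started from 8 to 12 counts in KMS34 untreated. CD52, CRLF2, RGS9 and the CT45A genes were named because their differences differ most between the lines, so that choice favours opposite directions. Over all genes past the filter, 63.5% had the same sign in both lines.

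The response was larger in KMS21, with 3.65 times as many genes at least 2-fold apart as in KMS34. Unequal depth was argued against: with all libraries thinned to 36535658 counts there were 3435 genes in KMS21 and 838 in KMS34, a ratio of 4.10. KMS34 RNA mixed into the KMS21 ambroxol library was also argued against, since 31 genes abundant in KMS34 and at 3 counts or fewer in KMS21 untreated had a median level in KMS21 ambroxol of 0% of that in KMS34 ambroxol, with 0.469% the highest. A response of the same shape at a uniformly smaller size in KMS34 stays open: with the common scale that suited most lists, 10 of the 33 tested lists lay off it beyond a 95% interval from resampled genes, but the bound (at least 10) was set after the list medians were seen and is only just met, genes of a list are not independent, and a first test on 2 picked lists was dropped. A difference between the lines in sensitivity to the drug also stays open and untested, as does a difference between single cultures, because each line had 1 treated culture.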

How the results depend on the processing

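The choices tried were fixed before the data were examined, except edgeR as the main test in place of the planned limma on log2(TPM + 1), chosen once counts were found, and DESeq2. Where a count moved, the cause was not tested unless fewer or more genes were tested. For the comparison across both lines, where edgeR called 0 genes, 8 other settings also called 0, while limma on log2(TPM + 5) called 1, edgeR without the low-value filter 88 and DESeq2 150. The number of genes at least 2-fold apart (3343 in KMS21, 916 in KMS34, 304 the same way in both) was 1046, 115 and 47 with log2(TPM + 5), which shrinks low genes by construction, 7238, 4304 and 840 without the filter, where more genes are counted, and 1954, 288 and 132 at a mean TPM of at least 5, where fewer are. With protein-coding genes only, 431 were 2-fold apart in KMS34 and 177 the same way in both. KMS21 had more such genes than KMS34 in each of these settings. The share of higher genes in KMS34, 61.6%, was 80.0% with log2(TPM + 5) and 62.2% with median-ratio scaling. The correlation across genes of the lines' differences (0.330) was 0.195 with log2(TPM + 0.1), 0.168 without the filter, and 0.437 both with log2(TPM + 5) and at a mean TPM of at least 5. In the limma settings TPM of 1 or less counts as 0, so a gene that crosses 1 TPM jumps by construction, most with log2(TPM + 0.1). The number of genes differing between the lines (6176) was 3923 at a mean TPM of at least 5, with fewer genes tested, and 4870 to 7904 in the other settings.

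The 23 lists called with the preset correlation became 21 to 24 in the other settings that kept it, 0 with an estimated correlation and 1 with fry. The estimated correlation had little power at 1 residual degree of freedom, so its 0 cannot decide whether a list moved. The preset correlation can call too many lists where genes of a list move together. Without the replicate block 24 lists and 0 genes were called, and genes differing between the lines numbered 5007. Of 2001 values of named genes across both lines under the alternatives, 72 passed the threshold, 41 of them with DESeq2 and 30 without the filter. Among genes whose estimate in the main test exceeded its SE, 3 values changed sign: MX1 (-0.0028 with log2(TPM + 5) and -0.22 without the replicate block) and RGS9 (-0.0045 without the replicate block). Sign changes of smaller estimates were not counted, such as that of CD7 (0.29 with edgeR and -1.23 with DESeq2). Leaving out a line gives a value with no test, so the count of genes called has none: of 184 named genes, 17 in KMS34 alone and 10 in KMS21 alone had the opposite sign to the fit of both lines. The median of all genes shifted by at most 0.045 over the settings. In the simulation with the estimated spread, 16.0% of genes at log2 1 and 92.0% at log2 2 were recovered. Its effects were the same in both lines and its spread followed expression level alone, so these shares may be too high for the real data. There, DDIT3 at log2 2.25 across both lines was not called (adjusted p = 0.38 with edgeR).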

Other observations

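Of the tests reported here, those of myeloid cells, of the feedback genes and of ATP6V0C were chosen only after the result was seen.

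Lists differed in how far KMS34 followed KMS21. The KMS34 median divided by the KMS21 median was 0.97 for the respiratory chain, 0.65 for ATF4 targets, 0.38 for lysosomal genes and 0.14 for both DNA replication and MYC-responsive ribosome biogenesis, lists picked after their values were seen. NF-kB targets, immediate early genes, fatty acid synthesis and the unfolded protein response had the greater median in KMS34. Some genes had nearly the same difference in both lines, such as TRIB3 (1.74 in KMS21 and 1.71 in KMS34), WIPI1 (1.30 and 1.32) and ICAM1 (1.13 and 1.11). BACH2, the gene of a repressor of plasma cell differentiation, went from 4.05 to 45.7 CPM in KMS21 (13.7 to 20.3 CPM in KMS34), and the cytokine receptor gene IL6R went from 192 to 853 CPM in KMS21 (388 to 380 CPM in KMS34). The pro-apoptotic gene BMF went from 23.4 to 177 CPM in KMS21 and from 40.9 to 38.5 CPM in KMS34. The differences between the lines were not tested gene by gene.

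Lysosomal and autophagy lists were higher after ambroxol in both lines. Transcript length and GC content were argued against: after their trend was removed in each line, the lowest percentile of the 4 lists among matched random lists, over both lines, was 99.87. Phagocytes mixed into the treated cultures were argued against by the myeloid markers, of which the highest reached 5.70 TPM in a treated library, while CTSB alone went from 84.1 to 1827 TPM in KMS21. The bound for the markers was set after their values were seen, which weakens this reading. That highest marker, CD68, itself a lysosomal gene, went from 54 to 232 counts in KMS21 and from 47 to 34 in KMS34. A transcriptional programme of the MiT/TFE factors, the family of TFEB, stays open: the median of their known targets FLCN, FNIP1, FNIP2, RRAGC and RRAGD, picked after their values were seen, exceeded that of 7 other genes of the lysosomal mTORC1 machinery (LAMTOR1 to LAMTOR5, RRAGA and RRAGB) by 1.69 in KMS21 and 0.89 in KMS34. Of these targets, FLCN, FNIP1 and RRAGC overlap other genes on the same strand. Among other known targets, MCOLN1 was at 0.03 in KMS21 and 0.28 in KMS34 and GPNMB at 0.96 and -0.01, and 14 of 19 V-ATPase genes were higher in both lines (adjusted p = 0.088, from 0.022 to 0.599 over the alternatives).

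ATP6V0C, at 2513870 to 2520218 on chromosome 16 (hg38), went from 711 to 63 counts in KMS21 and from 60 to 63 in KMS34, so in KMS21 it went against the direction of most V-ATPase genes. It overlaps 3 other genes on the same strand. The summed count of these genes and ATP6V0C went from 2842 to 5257 in KMS21, a log2 difference of 0.38, so the fall may come from how shared reads were divided. SPNS1, a lysosomal transporter gene chosen after its values were seen, went from 457 to 46 counts in KMS21 while its sum with 1 overlapping gene went from 2442 to 6110.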
